A study of Mus musculus with 12 samples.

How the data were processed

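Trimethylation of histone H3 at lysine 27 (H3K27me3) was profiled by CUT&RUN, in which an antibody directs a nuclease to cut and release the chromatin around its target, in single-cell suspensions of mouse epidermis. Per the labels' protocols, the cells came from females, a commercial CUT&RUN kit was used, and each animal gave an H3K27me3 library and an IgG background library. The labels give 12 libraries from 6 animals: 3 Cre-negative animals with floxed Utx alleles, called WT, and 3 Cre-positive animals with the same alleles, called Utx-cKO, in which Krt14-Cre deletes Utx (Kdm6a).

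The data analysed were 2 peak lists, 1 per genotype. Per the file headers, they are SEACR peak calls (the header spells the caller SECAR) made on data merged from all samples of the same group. Each line gives a peak's chromosome, start and end, its total signal, its maximum signal and the place of that maximum. The lists carry no column header, so the columns were read in the order of SEACR output. The signal values are the peak caller's score of each peak, the authors' own as deposited: total signal is the coverage summed over the peak and maximum signal is the highest coverage in it. The scale of the coverage and any normalization behind it are not given in the sources used here, and neither are the SEACR mode, control and threshold. Signal was therefore used only to describe, rank or filter peaks within a list, apart from the lowest total signal of each list and the common floor described below. Per the submitters' processing notes, Bowtie2 2.3.4.3, SAMtools 1.9, bedtools 2.27.1 and deepTools were used, and the builds mm10, GRCm38 and sacCer3 (yeast) were named. The notes as used here do not give the role of the yeast genome.

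In both lists every peak border fell on a 50 bp grid. All maximum signals were whole multiples, within 0.02 of a step, of a step of 0.260 in the WT list and 0.268 in the Utx-cKO list. Total signals of 1000000 and more carried fewer digits, which concerned 45 WT and 60 Utx-cKO peaks. Sequencing depth is unknown. Because each list pools its animals, no value has a replicate error, no p-value was computed, and values of the genotypes are given side by side. Values per library and IgG peaks were not analysed here. The 95% intervals of shares are exact Clopper-Pearson intervals. They cover counting error only, and neighbouring peaks are not independent.

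Genes were taken from the RefSeq annotation of GRCm38.p6, the build of the lists, on chromosomes 1 to 19 and X (49554 genes, of which 21631 protein-coding). The design fixed before the data were examined marked a gene by a peak within 2 kb of a transcription start, and matched random gene lists on promoter CpG content. The annotation used gave gene borders without strand, and no genome sequence was used. A gene was therefore called marked when a peak lay within 2 kb of either of its annotated ends, a change made before any gene result was seen. A peak was placed at a gene end by the same rule, otherwise within a gene or between genes, for protein-coding genes. Neighbouring genes can share a peak, so distinct peaks were counted as well.

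Peaks of the lists were compared by overlap of at least 1 bp. For comparison, the peaks of the other list were placed at random 100 times within the span of annotated genes of their chromosome. The share of each chromosome covered refers to the same span. A set of 22 gene lists (557 entries, 556 of them found) was fixed before the data were examined. It holds Hox genes, developmental transcription factors of other lineages, Wnt ligands, epidermal terminal differentiation, late cornified envelope, basal keratinocyte, hair follicle, sebaceous gland, retinoid, AP-1, cell cycle inhibitor, Polycomb and COMPASS-like complex, melanocyte, immune cell, fibroblast and endothelium, neuron, muscle, liver and housekeeping genes, X-linked genes subject to or escaping X inactivation, and imprinted genes. The number of marked protein-coding members was set against 10000 random lists of protein-coding genes with the same size, matched on 5 classes of gene length and on X linkage. These shares describe these 2 lists of peaks and are not tests of the genotypes. They are not adjusted for the 22 lists. The random lists were not matched on clustering, so the shares can overstate how rare a count is where neighbouring members share peaks. Nor were they matched on promoter CpG content as planned, so a share cannot be credited to the function that names a list.

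Named genes followed a rule fixed beforehand. It takes Kdm6a, Krt5, Krt14, Krt10, Cdkn2a and Cdkn2b always. From each gene list it takes up to 4 members whose marking differed between genotypes, or otherwise up to 4 marked in both, widest peak first. It also takes the 10 protein-coding genes per genotype with the widest peak and no peak of the other list in the gene or within 2 kb of it, and the 10 widest peaks of each list. Predicted gene models were left out, and some genes that the rule takes are not reported here.

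Alternatives fixed beforehand merged peaks within 5 kb, kept peaks of at least 1 kb, kept the top 50% of each list by total signal, left out chromosome X, required more overlap, extended peaks by 5 kb, equalised the number of peaks, and marked genes within 1 kb or 5 kb of an end or anywhere in the gene. Alternatives chosen after seeing the data applied a common floor to both lists, the lowest total signal of the WT list, either directly or in steps of the maximum signal, and required a peak at both gene ends. The common floor assumes that both lists have the same signal scale. Being the lowest WT value, it can remove peaks from the Utx-cKO list alone.

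Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Overlap counting was checked against bedtools 2.31.1. In a simulated second list, made from the WT list of 7826 peaks with peaks planted at 200 genes, all 200 were recovered among 49554 genes, and both tools counted 6325 overlapping peaks. The planted peaks lay within 2 kb of genes away from any WT peak, so their recovery checks the counting alone.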

Results

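H3K27me3, a repressive histone mark laid down by Polycomb complexes, was mapped by CUT&RUN in the epidermis of female mice with or without Utx. Utx (Kdm6a) is an X-linked demethylase of this mark, and it was deleted in keratin-14 expressing tissue by Krt14-Cre. The 12 libraries comprised 3 H3K27me3 and 3 IgG libraries from WT animals and the same numbers from Utx-cKO animals. The comparison asks how the distribution of H3K27me3 in epidermis differs when Utx is missing. The peak lists analysed pool the animals of a genotype, so none of the differences below could be set against the spread between animals, and sequencing depth is unknown. All positions refer to mm10 (GRCm38).

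The Utx-cKO list held more and slightly narrower H3K27me3 domains than the WT list. It contained 8914 peaks over 196 Mb, against 7826 peaks over 183 Mb in WT, a difference of 1088 peaks (1.14-fold) and 12.4 Mb (1.07-fold). The median width was 16500 bp (interquartile range 12250 to 24900 bp) in Utx-cKO and 17950 bp (13200 to 26900 bp) in WT. The Utx-cKO list also reached lower: its lowest total signal was 35753, against 40307 in WT. With the WT value as a common floor, 7686 Utx-cKO peaks remained, covering 182 Mb, so that the difference was -140 peaks and -1.90 Mb, and the median width was 17950 bp in both lists. That comparison was chosen after seeing the data and assumes that both lists share a signal scale. Its floor can remove Utx-cKO peaks but no WT peak.

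Most domains were found in both genotypes. Of the WT peaks, 6885 (88.0%, 95% interval 87.2 to 88.7%) overlapped a Utx-cKO peak, and of the Utx-cKO peaks 6991 (78.4%, 77.6 to 79.3%) overlapped a WT peak. Randomly placed peaks gave 19.4% (range 18.2 to 20.3% over 100 placements) and 17.4% (16.3 to 18.3%). The lists had 140 Mb in common, which was 76.5% of the length covered in WT and 71.7% of that covered in Utx-cKO. The peaks without a counterpart, 941 in WT and 1923 in Utx-cKO, were mostly weak ones, and at the common floor they numbered 1300 in WT and 1158 in Utx-cKO. Without that floor, their median total signal lay at percentile 17.4 of the WT list and 18.2 of the Utx-cKO list, against 55.6 and 60.0 for overlapping peaks. Of the Utx-cKO peaks without a counterpart, 765 (39.8%) lay below the lowest total signal of the WT list. With 50% of both peaks required to overlap, the shares were 66.8% in WT and 58.6% in Utx-cKO.

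**Figure D1:**
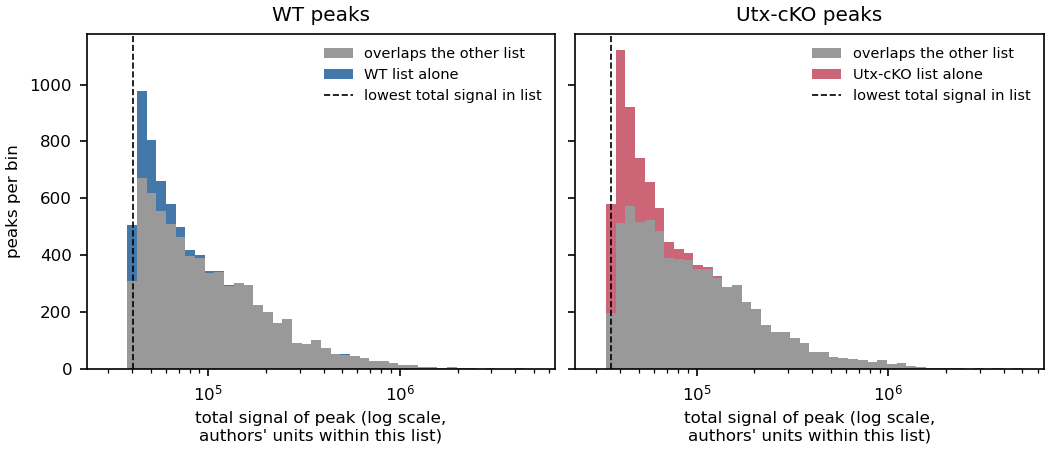
Number of peaks (vertical axis) by total signal (horizontal axis, log scale, in the authors' units within each list) for the WT and the Utx-cKO list. Grey bars are peaks that overlap the other list and coloured bars the 941 WT and 1923 Utx-cKO peaks that do not, which crowd towards the lowest total signal of each list (dashed line).

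Chromosome X was the most densely covered chromosome in both genotypes. In females, the inactive X is known to carry H3K27me3. Peaks covered 33.6% of the X gene span in WT and 34.6% in Utx-cKO, against 5.17% and 5.60% of the autosomes, which is 6.50 and 6.18 times as much. Among autosomes, coverage ran from 3.46% (WT) and 3.92% (Utx-cKO) on chromosome 16 to 6.92% and 7.65% on chromosome 9. X held 1700 WT peaks and 1880 Utx-cKO peaks, and 31.2% and 30.2% of the covered length. By number of peaks its share was 21.7% (20.8 to 22.7%) and 21.1% (20.2 to 22.0%). X domains were wider and lower than autosomal ones. Their median width was 24750 bp in WT and 22125 bp in Utx-cKO, against 16800 and 15500 bp on autosomes, and their median maximum signal was 9.34 and 9.63, against 16.9 and 14.99. Of the 10 widest peaks, 8 in WT and 9 in Utx-cKO lay on X. The widest in both lists covered Pola1, which encodes the catalytic subunit of DNA polymerase alpha (X, 93354401 to 93615850 in WT and 93299401 to 93610900 in Utx-cKO).

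**Figure D2:**
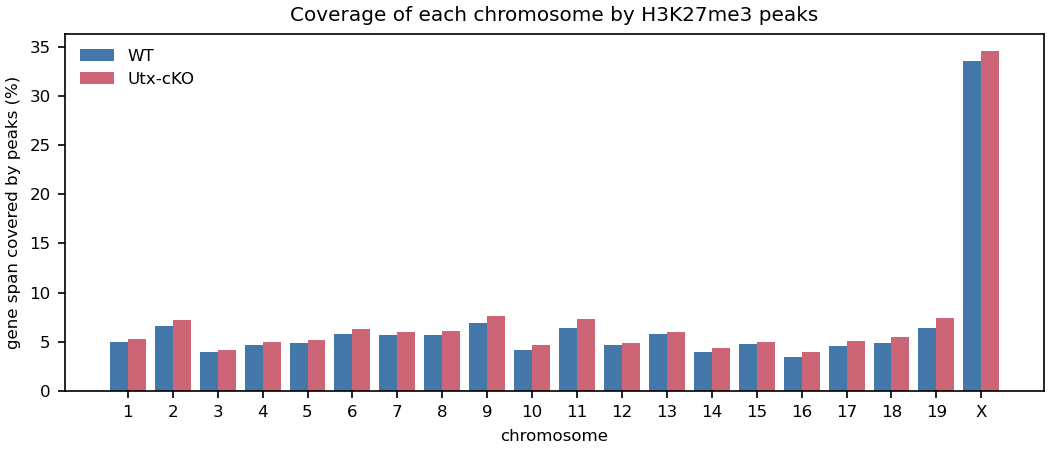
Share of the span of annotated genes covered by H3K27me3 peaks (vertical axis, percent) on chromosomes 1 to 19 and X (horizontal axis), for the WT and the Utx-cKO list. X stands at 33.6% and 34.6%, and no autosome exceeds 7.65%.

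Genes known to be silenced on the inactive X were marked in most cases, and the number of marked escape genes lay below the median of random X-linked lists. Of 24 X-linked genes subject to inactivation, 19 were marked in WT and 22 in Utx-cKO, against a median of 18 in random lists in both genotypes. In random lists, 31.5% and 3.45% held as many. The 3 genes marked in Utx-cKO alone were Pdha1, a subunit of pyruvate dehydrogenase, Bcor, a transcriptional corepressor, and Atp7a, a copper transporter. Bcor and Atp7a each had 2 WT peaks within the gene or 2 kb of it, and by peaks anywhere in the gene or within 2 kb the list stood at 21 in WT and 22 in Utx-cKO. The Pdha1 peak (X, 159971751 to 160137850) was 77.5% covered by WT peaks that ended short of the gene. Of 10 genes known to escape inactivation, 3 were marked in WT (Mid1, Utp14a and Car5b) and 4 in Utx-cKO, with Kdm5c, an H3K4 demethylase, added. The Kdm5c peak (X, 152223901 to 152232800) ended before the gene's border at 152233198 and stood at percentile 8.60 of its list. A wide WT peak over Smc1a and Iqsec2 ended next to it, at 152223300. Random lists matched to the 8 protein-coding members held a median of 6, and 3.95% (WT) and 10.97% (Utx-cKO) held as few. Kdm6a itself (X, 18160862 to 18279936) had no peak in either list, which says nothing about its deletion. At the common floor the escape genes stood at 3 in WT and 2 in Utx-cKO, without Kdm5c. With a peak required at both gene ends, the inactivated genes stood at 14 in WT and 12 in Utx-cKO.

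At the level of genes, both lists marked largely the same set. Of 21631 protein-coding genes, 3520 (16.3%) were marked in WT and 3818 (17.7%) in Utx-cKO, 3139 of them in both, where independent lists of these sizes would share 621. That value ignores the denser marking of X. Taken apart, both lists marked 2643 autosomal genes, against 468 if independent, and 496 X genes, against 322. The Utx-cKO list alone marked 679 genes and the WT list alone 381. The peak at such a gene overlapped a peak of the other list in 187 (49.1%) of the WT genes and 202 (29.7%) of the Utx-cKO genes. At the common floor, 473 genes were marked in Utx-cKO alone and 466 in WT alone. Of the peaks, 40.4% (39.3 to 41.5%) in WT and 39.1% (38.1 to 40.1%) in Utx-cKO lay at a gene end, 20.6% and 20.9% within a gene and 39.0% and 40.0% between genes.

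Regulators of development outside the epidermis carried the mark in both genotypes. Of 87 developmental transcription factors of other lineages, 86 were marked in each list and 85 in both, against a random median of 11 in WT and 12 in Utx-cKO. The exceptions were Pax6, an eye and neural factor, marked in WT alone, and Gata4, a heart and endoderm factor, marked in Utx-cKO alone. The Pax6 peak (chromosome 2, 105632001 to 105696100) had a maximum signal of 94.7, lay at percentile 99.8 of the WT list by total signal, and was 13.4% covered by Utx-cKO peaks. The Gata4 peak (chromosome 14, 63224101 to 63313500) was 89400 bp wide with a maximum signal of 78.4, lay at percentile 99.9 of the Utx-cKO list, and overlapped no peak of the WT list analysed here. A single strong domain per list is no measure of a difference between animals.

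Of 39 Hox genes, 27 were marked in WT, on 6 peaks, and 29 in Utx-cKO, on 8 peaks. A domain over Hoxc6 to Hoxc13 was among the widest of both lists (chromosome 15, 102750001 to 102998950 in WT and to 103010200 in Utx-cKO). Hoxa4, marked in Utx-cKO alone, had a peak at percentile 1.16 of that list by total signal. At the common floor, 25 Hox genes were marked in Utx-cKO and 27 in WT. Of 19 Wnt ligands, 8 were marked in WT and 10 in Utx-cKO, with Wnt5a and Wnt11 in Utx-cKO alone, at percentiles 5.23 and 15.9, and the common floor left 7 in Utx-cKO against 8 in WT. For the Hox genes and the developmental transcription factors 0% of random lists held as many marked genes in either genotype, and for the Wnt ligands 0.15% (WT) and 0.01% (Utx-cKO) did. The random lists ignore clustering and promoter CpG content, and the marked Hox genes share few peaks.

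Krt5 and Krt14, the keratins of basal cells, and Krt10, a keratin of suprabasal cells, had no peak at either end in either list. Of 23 basal keratinocyte genes, 2 were marked in WT (Dst and Sox6) and 3 in Utx-cKO, where Itga3, an integrin subunit, was added, and 21.5% and 35.7% of random lists held as few. Of 53 genes of epidermal terminal differentiation, 3 were marked in WT and 7 in Utx-cKO, against a random median of 7 in both, and 7.99% and 52.0% of random lists held as few. Tchh, Cnfn and Elovl4 were marked in both. Marked in Utx-cKO alone were Tgm3 and Tgm5, transglutaminases that crosslink the cornified envelope, Cdsn, an adhesive protein of corneodesmosomes, and Hal, which makes urocanic acid. An excess of 4 genes or more in Utx-cKO over WT occurred in 3.67% of random lists, unadjusted for the 22 gene lists. The peaks at Tgm5 (chromosome 2, 121044751 to 121062100), Hal (chromosome 10, 93486551 to 93498050), Cdsn (chromosome 17, 35557501 to 35571250) and Tgm3 (chromosome 2, 130032901 to 130048500) stood at percentiles 43.9, 29.9, 3.94 and 1.51 of their list by total signal. Each peak lay at a single end of its gene. The Cdsn peak began beyond the gene's border at 35557180, and the Tgm3 peak lay inside the gene, near its border at 130050399. Without strand, these ends cannot be told to be transcription starts. At the common floor 5 of the 53 genes were marked in Utx-cKO and 3 in WT, Tgm5 and Hal being the difference. With a peak required at both gene ends, none of Tgm3, Tgm5, Cdsn and Hal was marked in Utx-cKO alone. That follows from each peak lying at a single end, so this rule cannot decide on them. The top 50% of each list leaves out these 4 peaks because of their percentiles, so that setting cannot decide on them. Of 21 late cornified envelope genes, the neighbours Lce3a, Lce3b, Lce3c and Lce3d were marked in both genotypes, on 2 peaks in each, against a random median of 2 genes.

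Of 30 hair follicle genes, 17 were marked in each genotype and 15 in both, and 0% of random lists held as many. The follicle keratins Krt72 and Krt73 shared a peak in WT alone (chromosome 15, 101786451 to 101806950), at percentile 22.1 of that list by total signal. Krt75 and Krt28, also follicle keratins, were marked in Utx-cKO alone, at percentiles 53.0 and 29.8. Of 18 sebaceous gland genes, the same 9 were marked in both, among them the wax synthases Awat1 and Awat2 and the melanocortin receptor Mc5r, and 0.18% (WT) and 0.53% (Utx-cKO) of random lists held as many. Of 26 genes of retinoid metabolism and signalling, 10 were marked in WT and 11 in Utx-cKO, where Crabp2, a retinoic acid binding protein, was added, and 0.22% and 0.15% of random lists held as many. At the common floor Crabp2 and Itga3 were not marked.

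Among 7 cell cycle inhibitors, the neighbours Cdkn2a and Cdkn2b shared a peak in both genotypes (chromosome 4, 89264901 to 89310600 in WT and 89264851 to 89310650 in Utx-cKO), at percentile 99.8 of both lists, and 19.2% (WT) and 23.7% (Utx-cKO) of random lists held as many. Of 12 AP-1 factors, Batf and Batf3 were marked in both and Atf3 in WT alone. The Atf3 peak was 86.8% covered by Utx-cKO peaks, and with gene ends within 5 kb the same 3 factors were marked in both. Of 32 Polycomb and COMPASS-like complex genes, 4 were marked in WT and 5 in Utx-cKO. Rbbp7, Pcgf1 and Phc1 were marked in both, and Cbx8 in WT alone, while Kmt2a was among those marked in Utx-cKO alone. The Cbx8 peak was 54.6% covered by Utx-cKO peaks and began at 119041401, beyond the gene's border at 119040913. The Kmt2a peak overlapped no WT peak and began at 44883301, beyond the gene's border at 44881352. As many marked genes were held by 15.1% (WT) and 47.6% (Utx-cKO) of random lists for AP-1 factors, and by 90.9% and 84.1% for the complex genes.

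**Figure D3:**
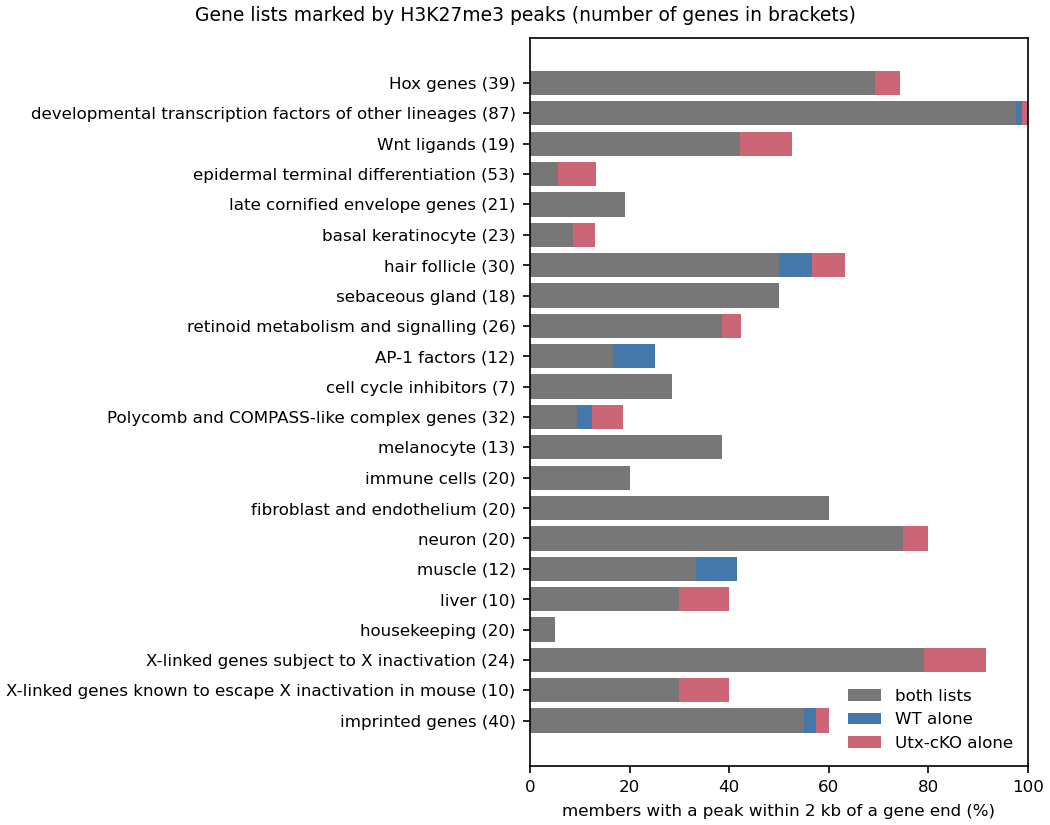
Share of the members of 22 gene lists (rows, number of genes in brackets) with a peak within 2 kb of a gene end (horizontal axis, percent), split into members marked in both lists, in WT alone and in Utx-cKO alone. The grey part, marked in both, is the longest for the 87 developmental transcription factors, and 3 of 53 terminal differentiation genes are marked in both.

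Markers of other cell types gave nearly the same counts in both genotypes. Of 20 neuronal genes, 15 were marked in WT and 16 in Utx-cKO (Nefm, a neurofilament, in Utx-cKO alone), and of 20 fibroblast and endothelial genes the same 12 were marked in both, including Prrx1, Vim, Twist1 and Twist2. For these 2 lists 0% of random lists held as many. Of 13 melanocyte genes 5 were marked in both, including Kit and Dct, and of 20 immune genes 4, namely Cd207, Cd3d, Cd3e and Cd3g. Cd3d and Cd3g shared a peak in each list. As many were held by 9.34% (WT) and 12.3% (Utx-cKO) of random lists for melanocyte genes, and by 25.7% and 34.2% for immune genes. At the common floor 3 melanocyte genes were marked in Utx-cKO and 5 in WT. Of 12 muscle genes 5 were marked in WT and 4 in Utx-cKO, with Myh6 in WT alone. Of 10 liver genes 3 were marked in WT and 4 in Utx-cKO, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, in Utx-cKO alone. For muscle genes 0.91% (WT) and 6.37% (Utx-cKO) of random lists held as many, and for liver genes 29.6% and 12.1%. Of 20 housekeeping genes 1 was marked in both, the X-linked Nono. Of 40 imprinted genes 23 were marked in each list and 22 in both, with Meg3 in WT alone and Peg12 in Utx-cKO alone. The Meg3 peak was 53.1% covered by Utx-cKO peaks. At the common floor 23 imprinted genes were marked in WT and 22 in Utx-cKO, without Peg12. Of the 33 protein-coding members 19 were marked in WT and 20 in Utx-cKO, and 0% of random lists matched to them held as many.

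At most genes marked in 1 genotype with the widest peaks, the peak was partly covered by peaks of the other list. In WT alone these were Acr, Pja1, Lyzl6, Tsen15, Limch1, Slc10a3, Mid1ip1, Elp4, Pax6 and Gnl2. Elp4 and Pax6 shared the peak described above, and the other 8 peaks were covered by Utx-cKO peaks over 53.4% (Gnl2) to 93.6% (Slc10a3) of their length. In Utx-cKO alone they were Pdha1, H2al1a, Gata4, Exoc3l4, Zfp92, Rbmx, Timp4, Sdsl, Ifna5 and Ifne. Apart from Gata4, their peaks were covered by WT peaks over 41.5% (Rbmx) to 86.3% (H2al1a) of their length. Among the 783 WT and 892 Utx-cKO peaks in the top 10% of total signal, 99.7% and 99.9% overlapped the other list by at least 1 bp, and 12 and 24 were covered over less than 50% of their length. A further strong pair without a counterpart, picked after its values were seen, lay around Nr2f1, an orphan nuclear receptor of neural development, in WT (chromosome 13, 78163951 to 78198400 and 78201701 to 78231850), at percentiles 99.4 and 96.9.

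**Figure D4:**
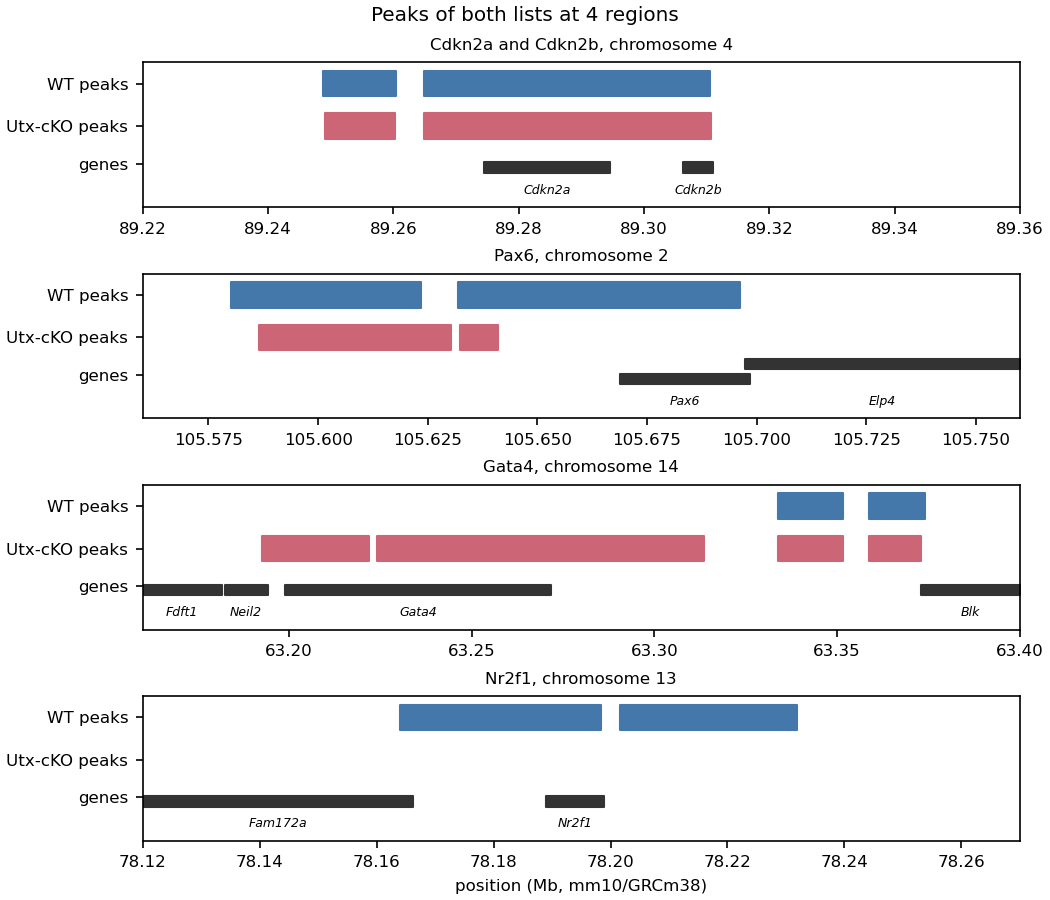
Peaks of the WT list and the Utx-cKO list and annotated protein-coding genes (bars) at 4 regions along the genome (horizontal axes, position in Mb). The Cdkn2a and Cdkn2b domain is in both lists, the domain over Pax6 and those at Nr2f1 have little or no counterpart in the Utx-cKO list, and the Gata4 domain of 89400 bp has none in the WT list.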

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

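The tests with a common floor of total signal, directly or in steps of the maximum signal, and with peaks at both gene ends were chosen after seeing the data. The others were fixed before. The excess of Utx-cKO peaks and covered length kept its direction when peaks within 5 kb were merged, peaks under 1 kb removed or X left out. Keeping the top 50% of each list (3913 and 4457 peaks, a difference of 544) says nothing about the number of peaks, since it divides both lists alike. The excess turned to -140 peaks and -1.90 Mb at the common floor, and to -425 peaks and -5.43 Mb with that floor in steps. The common floor, being the lowest WT value, removed 1228 Utx-cKO peaks and can remove no WT peak. The share of overlapping WT peaks was 82.0% with 50% of the peak covered, 66.8% with 50% of both peaks covered, 89.97% with the other list extended by 5 kb, 84.0% with equal numbers of peaks and 83.4% at the common floor. For Utx-cKO it was 72.9%, 58.6%, 81.6%, 84.2% and 84.9% in the same order, and 77.5% without X. The higher share was that of WT without the floor and that of Utx-cKO at it, and with equal numbers of peaks that of Utx-cKO was again the higher. Genes marked in both numbered 1073 with peaks at both ends, and those in Utx-cKO alone 342. The excess of genes marked in Utx-cKO over WT was 173 in the top 50%, 88 with both ends and 7 at the common floor. The share of X was 21.7% (WT) and 21.1% (Utx-cKO) by number of peaks. For gene lists, the difference of Utx-cKO minus WT turned to -2 for Hox genes, -1 for Wnt ligands and -1 for escape genes at the common floor. It turned to -1 for Polycomb and COMPASS-like genes in the top 50% and with both ends, to -2 for genes subject to X inactivation and to -1 for escape genes with both ends. Of the 22 lists, 17 stayed within 1.5-fold of their difference with gene ends within 5 kb and 20 with the whole gene. In the top 50% 10 did, with both ends 8 and at the common floor 13. Lists without a difference that stayed without one are counted here, so these numbers overstate how stable the differences were. Among lists with a difference, only AP-1, neuron and liver genes kept theirs in the top 50%. At the common floor, only AP-1, Polycomb and COMPASS-like, neuron, muscle and X-inactivated genes did. Apart from the floor, the cause was not tested. No paired analysis was possible because the result comes from pooled lists and the genotypes are different animals. Leaving out each replicate, DESeq2 or other scaling per library, and the authors' gene annotation were not run, since the lists used hold no such values. Depth is unknown and sets no stated limit.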

Other observations

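The common floor, its test on the number of peaks and the tests of the strong domains were chosen after the result was seen, while what covered length at that floor and the terminal differentiation genes would show was set down before those values were computed. Other gene families were picked by symbol after the data were seen, and their counts were not set against random lists. Of 34 homeobox genes (the Lhx, Nkx and Irx families and the sine oculis homologues), 31 were marked in WT and 32 in Utx-cKO, of 22 fibroblast growth factors 16 in each, and of 44 forkhead genes 25 in each. Potassium channel genes (Kcn) were marked in 48 of 94 cases in WT and 53 in Utx-cKO. All 48 were marked in both, and Kcnh2, Kcnn4, Kcne3, Kcnf1 and Kcnk18 in Utx-cKO alone. Large families of sensory receptors gave 47 (WT) and 53 (Utx-cKO) of 1110 olfactory receptor genes, and 5 and 4 of 353 vomeronasal receptor genes. The clustered protocadherins had 1 marked gene of 52 in both. Of 53 keratin genes 8 were marked in WT and 11 in Utx-cKO, and of 397 Zfp zinc finger genes 42 in each, 32 of them in both. Ribosomal protein genes went the other way, with 5 of 87 marked in WT and 2 in Utx-cKO. Keratin-associated protein genes gave 3 and 4 of 56, beta-defensin genes 5 and 7 of 42, and Gpr receptor genes 26 and 28 of 75. The Utx-cKO counts at the common floor were 31 for the homeobox genes, 52 for potassium channels, 46 for olfactory receptors, 3 for vomeronasal receptors, 11 for keratins, 37 for Zfp genes, 1 for ribosomal proteins, 4 for keratin-associated proteins, 6 for beta-defensins and 27 for Gpr receptors, with the WT counts as given. The Utx-cKO counts of fibroblast growth factor, forkhead and protocadherin genes were the same at that floor.

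The Utx-cKO list held 13 peaks shorter than the shortest WT peak (3100 bp), 11 of them without overlap with a WT peak. The tallest had a maximum signal of 354 over 2450 bp on chromosome 3 (8244651 to 8247100). A pair of 1000 and 900 bp on chromosome 1 (171069301 to 171070300 and 171078351 to 171079250) lay within 20 kb of 15 tRNA genes.

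More peaks were listed in Utx-cKO than in WT. The lower floor of the Utx-cKO list may account for this: at the lowest total signal of the WT list, 7686 Utx-cKO peaks were left against 7826 in WT. Wider H3K27me3 coverage after loss of the demethylase was set against this, and at that floor the covered length in Utx-cKO was 0.990 times that in WT. Wider coverage stays open, because the scale of the signal and the SEACR threshold are not given in the sources used here and the pooled lists used here show no spread between animals. The floor can also lower the Utx-cKO values alone, since no WT peak lies below it.

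Domains at Nr2f1 and Pax6 in WT and at Gata4 in Utx-cKO were strong in one list and had little or no counterpart in the other. They were picked as peaks in the top 10% by total signal with less than 20% of their length covered by the other list. The weakest stood at percentile 96.9 of its own list, and their total signal was 12.4 to 47.8 times the floor of that list. These values follow from the way they were picked and leave open whether the signal of the other genotype lay just under its own floor. Shifted or split borders are argued against for the 3 domains without overlap, at Nr2f1 and Gata4, of which 0 had a peak of the other list within 5 kb, but not for the Pax6 domain, covered over 21.9% of its length by the other list extended by 5 kb. A difference in H3K27me3 between the genotypes may be the source, and it cannot be told apart from a call or a list entry lost in handling, because in the pooled lists used here 0 libraries have values of their own.

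The terminal differentiation genes Tgm3, Tgm5, Cdsn and Hal were marked in Utx-cKO alone. The lower floor of the Utx-cKO list may account for part: at the common floor, 2 genes, Tgm5 and Hal, were still marked in Utx-cKO alone. With peaks required at both gene ends none of the 4 was, and the excess over WT was 1 gene, Tchh. Each of the 4 peaks lay at a single gene end, so that setting cannot decide on them. The top 50% of each list leaves out all 4 because of their percentiles, so its excess of 1 gene cannot decide on them. A random choice of genes gave as large an excess in 3.67% of lists, which, among 22 lists, leaves chance open. A gain of H3K27me3 at or near these genes after loss of Utx stays open, untested without values per animal.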
